A study of Mus musculus with 2 samples.

How the data were processed

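H3K9me3 ChIP-seq was made from forebrain of mouse embryos at day 14.5 (strain label B6NTac;B6NCrl/Lap), in 2 biological replicates of 24 and 34 pooled embryos with 2 technical replicates each, sequenced on Illumina HiSeq instruments of 2 models with a size range of 300 to 500 per the labels. Both replicates formed 1 group. The authors deposited 4 peak lists in narrowPeak format on mm10: 1 for each replicate, 1 for both replicates pooled and 1 of replicated peaks. The deposited descriptions derive each replicate's list from its filtered alignments and from further files, 2 for replicate 1 and 1 for replicate 2, whose role they do not name; tracks described as fold change over control were derived from the same files. The replicated list was derived from the pooled list and both replicates' lists by a rule that is not given in the sources used here. The aligner, the peak caller, their versions and the calling threshold are not given in the sources used here either.

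The deposited lists hold, per peak, a signal (the enrichment value of the authors' call, not defined further by them), the neg_log10_p of the authors' caller for its p and likewise -log10 of its q, and, as another column the authors deposited under the unit other, the offset of the summit in bp from the start. The values were used as deposited, with no further normalization. Alignments and signal tracks were not analysed here, and the read depth of each replicate is unknown. The smallest -log10 p was 2.01 in replicate 1 and 2.05 in replicate 2, and 27.7% and 36.3% of their peaks had a q of at most 0.05, so the replicates' own lists hold many weak calls.

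Positions were compared with the GRCm38 genome sequence and the GENCODE M21 basic annotation, for chromosomes 1 to 19, X and Y (21 chromosomes). Peaks on scaffolds were left out of these comparisons, and were kept in the totals of each list, in the comparison of the replicated with the pooled list and among the highest peaks. Peaks are printed with starts counted from 1. A peak was found in another list when it overlapped one of its peaks by at least 1 bp. Moved lists were made by shifting all peaks of a chromosome around it by 1 random distance of at least 1 Mb, which keeps widths and spacing: 10000 shifts for gene lists, 1000 for replicate overlap and annotation, and 100 for sequence and for the overlap rules of 50%. Shift tests were two-sided (the permutation p of the text), and p-values were adjusted by Benjamini-Hochberg over the 24 gene lists and over the 4 annotation classes, with a threshold of 0.05. Intervals of shares are exact Clopper-Pearson intervals at 95%. They take peaks or genes as independent, which neighbouring ones are not, and so are too narrow where peaks or genes cluster. Promoters were within 2 kb of a transcript start, then exons, introns and intergenic sequence in that order, by summit. Gene bodies were extended by 2 kb. The transcript with the longest spliced length gave the first and last exon of a gene. Domains joined peaks up to 5 kb apart. Lists given by a symbol pattern took protein-coding genes, and lists of named genes took any gene type; of the 24 named members of the H3K9 methylation list, 23 gene models were found. No comparison between groups, and so no pairing of samples, was possible with 1 group.

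The gene lists, the tests and the alternatives were fixed before the data were examined. The text names the 25 protein-coding genes with the most covered sequence and a peak in both replicates' lists, up to 5 members of each gene list that passed and up to 3 of the others, all imprinted members with a peak, the 10 peaks with the highest enrichment value and the 10 longest domains. Imprinted members without a peak, nearest genes and further peaks were named after their values were seen. The alternatives were the pooled list, either replicate alone, peaks with -log10 q of at least 5, other overlap rules (50% of the peak, reciprocal 50%), the strongest peaks of each replicate, merged peaks, promoters alone, gene bodies without extension, at least 500 bp covered, Fisher's exact test in place of shifts, any overlap in place of the summit, merging distances of 1 and 20 kb and ungapped chromosome lengths. Replicated peaks that overlap a peak of each replicate, and random placement of peaks within their own gene (1000 placements), were added after the data were examined.

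The tests were tested on simulated data. Replicated peaks moved at random gave an adjusted p below 0.05 in 0% of 480 list tests and an unadjusted one in 0.833%. The unadjusted share lies below the threshold, so the list test was conservative on these lists. They were moved in the same way as in the test, so this checks the computation and not the choice of shifts. With a peak of median width planted in 30% of the members of 1 list, that list was called in 80% of 20 runs, and in 0 of 3 runs for the clustered protocadherins, whose members share 1 place. With 30.0% of the replicate 1 peaks copied, the overlap found was 30.3% on average. Moving 10% of peaks to gene starts raised the promoter share by 8.81 percentage points on average and was called in 10 of 10 runs; without this, 3 of 40 class tests had an unadjusted p below 0.05. A peak much narrower than the median, planted in each last exon of 418 zinc finger genes, gave a last exon share of 100%. That share was fixed by the planting and checks the counting alone. A single such peak planted at random in each gene gave 23.7%. The real peaks placed at random within their genes gave 42.4%, so 23.7% is not the background of the result. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.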

Results

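H3K9me3, a histone mark of silenced chromatin, was mapped by ChIP-seq in mouse forebrain at embryonic day 14.5. The series held 1 group of 2 biological replicates, each a pool of male and female embryos: replicate 1 came from 24 embryos and replicate 2 from 34. No second tissue, stage or treatment and no control library was among the samples, so the comparisons were of peak positions against the same peaks moved along their chromosomes, and of the replicates with each other. The labels do not state a question beyond the map itself. The deposited peak lists held 27541 peaks for replicate 1 (7.32 Mb, median width 217 bp) and 23720 for replicate 2 (7.49 Mb, median width 252 bp). The pooled list held 36989 peaks, and the replicated list held 10045 peaks that covered 5.42 Mb, with a median width of 434 bp. Its peaks on chromosomes, called in a narrow format that can split broad regions of the mark, covered 0.198% of their ungapped length. Peaks are given by the authors' enrichment value, whose median was 3.12 in replicate 1, 3.48 in replicate 2 and 3.58 in the replicated list. Read depth is unknown from these files, so the intervals below cover the counting of peaks and genes only. Positions are in mm10, and unless another list is named, peaks are those of the replicated list.

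The clustered protocadherins, the zinc finger genes, the imprinted genes and the vomeronasal receptors were the gene groups with the smallest adjusted permutation p against moved lists. Of 24 gene lists fixed before the data were examined, 6 had more members with a peak than in 10000 circular shifts of the list (two-sided, adjusted over the lists alone), and 0 had fewer. Lists with small means could not be called fewer. For ribosomal protein genes, 0 of 80 members against a mean of 2.23 gave an unadjusted permutation p of 0.232. A member counted when a peak overlapped its gene body extended by 2 kb on each side. In all, 1938 of 21938 protein-coding genes (8.83%) had such a peak, against 4462 with a replicate 1 peak, 3530 with a replicate 2 peak and 2480 with a peak in both of these lists. Lists of clustered genes are few independent places, which the shifts allow for and the number of members does not show.

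**Figure D1:**
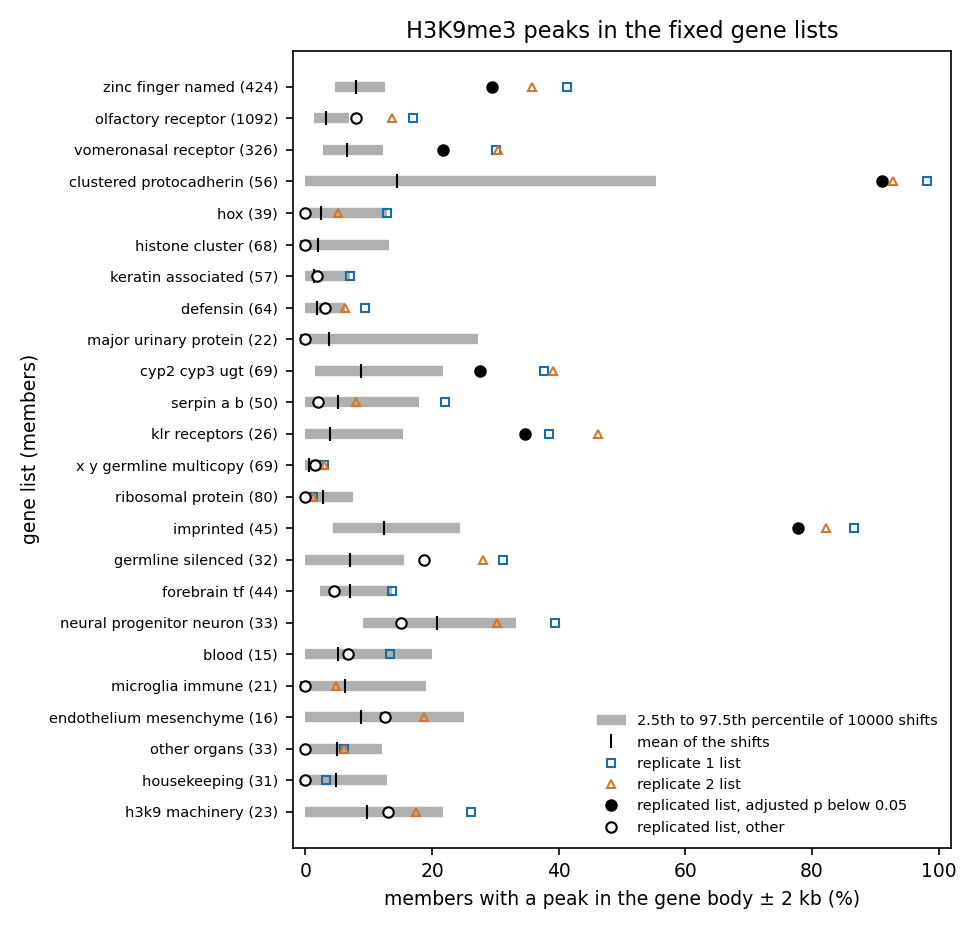
Percent of the members of each gene list (number of members in brackets) with an H3K9me3 peak in the gene body or within 2 kb. Filled circles are the lists that passed the test in the replicated list and open circles the others, squares and triangles are the lists of replicates 1 and 2, and grey bars span the central 95% of 10000 shifts of the replicated list. Clustered protocadherins (91.1%) and imprinted genes (77.8%) lie farthest above their shifts.

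Clustered protocadherins, cell surface proteins that give neurons individual identities, had a peak in 51 of 56 members (91.1%), against a mean of 8.09 under the shifts (6.30-fold, adjusted permutation p = 0.0012, with an unadjusted p of 0.0002, the smallest the shifts can give). Replicate 1 had a peak in 55 members (2.89-fold over the shifts of its own longer list) and replicate 2 in 52 (3.07-fold). The region on chromosome 18 from 36890286 to 37842134 held 279 peaks, with 416 in replicate 1 and 424 in replicate 2. Pcdhga1 (18:37661793-37841873) had the most covered sequence of any named protocadherin, 85778 bp in 74 peaks, followed by Pcdhga2 (81663 bp), Pcdhga3 (79105 bp), Pcdhgb1 (75535 bp) and Pcdhga4 (73611 bp). The annotated bodies of these genes overlap up to nearly the same 3' end. A peak over the first exon of a later gene therefore counts for each gene that starts before it. The highest enrichment value of the region, 8.81, was at 18:37731424-37732680, over the first exon of Pcdhgb5. Over the whole extended body of Pcdhgb5 the highest value was 7.38 in replicate 1 and 9.05 in replicate 2. Pcdhga9 had the same highest value in replicate 1 (7.38) and Pcdhgb6 in replicate 2 (9.05). Both genes start 3' of that peak, so these are not shown to be its values in the replicates. The genes ranked by covered sequence also included Pcdhgb2, Pcdhga5, Pcdhga6, Pcdhga7, Pcdhgb4, Pcdhga8, Pcdhga9 and Pcdhgb6, and Pcdha1 to Pcdha6, of which Pcdha1 had 43798 bp in 68 peaks with a highest value of 5.43. The predicted genes Gm42416, Gm37013 and Gm37388, whose annotated span runs across these clusters, took the first places of that ranking, with 189368 bp in Gm42416. Of the 25 protein-coding genes with the most covered sequence, 23 lay in this region. The others were Mroh2a (1:88226986-88262289), with 31561 bp in 8 peaks, and Skint5 (4:113477891-113999503), a member of a family of skin T cell ligands, with 26773 bp in 60 peaks.

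**Figure D2:**
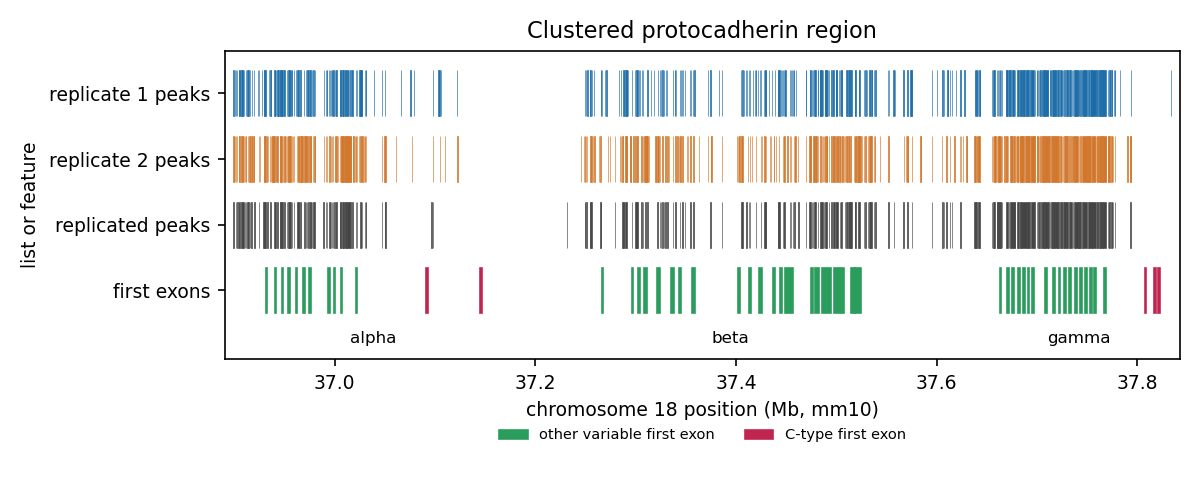
Peaks of both replicates and of the replicated list along the clustered protocadherin region of chromosome 18 (x axis, Mb), with the first exons of the alpha, beta and gamma clusters below. Each bar spans a peak or exon, with a thin outline so that narrow peaks stay visible. The 5 C-type first exons hold no peak in any of the lists drawn.

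Zinc finger genes, many of which encode KRAB repressors of transposable elements, had a peak in 125 of 424 members (29.5%, exact 95% interval 25.2 to 34.1), against a mean of 33.8 under the shifts (3.70-fold, adjusted permutation p = 0.0012). Replicate 1 gave 175 members (2.14-fold over the shifts of its own longer list) and replicate 2 gave 152 (2.22-fold). Of the 125 members, 119 had a peak in each replicate's own list. The members with the most covered sequence were Zfp873 (10:82048123-82064745, 15199 bp, highest enrichment value 7.97), Zfp606 (7:12478293-12496235, 14875 bp, 7.71), Zfp110 (14804 bp, 6.62), Zfp943 (13554 bp, 5.10) and Zfp369 (13486 bp, 6.67). By chromosome, 25 of 103 members on chromosome 7 had a peak, 16 of 47 on chromosome 17, 15 of 32 on chromosome 4, 14 of 43 on chromosome 13 and 11 of 20 on chromosome 9. Counted within 2 kb of the outer gene start alone, 12 members had a peak (adjusted permutation p = 0.832). The other alternatives by shifts gave adjusted permutation p from 0.0012 to 0.0016. Fisher's exact test, which does not allow for clustered genes, gave an adjusted p of 5.98e-34.

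Within zinc finger genes the peaks lay over the last exon more often than its length would give, though most peak sequence lay outside it. Of 119 zinc finger genes with at least 2 exons and a peak in the gene body, 93 (78.2%, exact 95% interval 69.6 to 85.2) had a peak in the last exon, and 1 had one in the first exon. The exact binomial test of last against first exon gave p = 9.59e-27 (two-sided). Other protein-coding genes with a peak had it in the last exon in 185 of 1597 cases (11.6%, 10.1 to 13.3) and in the first exon in 118 cases (7.39%). The last exon share differed between these groups by Fisher's exact test (odds ratio 27.3, p = 5.31e-56, two-sided). Zinc finger genes in clusters are not independent, and long last exons catch more peaks by chance: with the peaks of each gene placed at random within it, a mean of 50.5 genes (42.4%) and at most 66 had a peak in the last exon. The last exons held 39.0% of the peak sequence and 9.59% of the gene sequence. This comparison with random placement was chosen after the data were examined (one-sided permutation p = 0.001, the smallest that 1000 placements can give).

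Imprinted genes, expressed from the copy of a single parent, had a peak in 35 of 45 members (77.8%), against a mean of 5.62 under the shifts (6.23-fold, adjusted permutation p = 0.0012). Replicate 1 gave 39 members (3.05-fold over the shifts of its own longer list) and replicate 2 gave 37 (3.44-fold). All 35 had a peak in each replicate's own list. The 45 genes form 33 separate regions, of which 24 held a peak (28 in replicate 1 and 25 in replicate 2). The highest enrichment values were at Plagl1 (5.60, 10:13090202-13091844), Gnas and Nespas (5.10, 2:174295112-174295869), Mest (5.02, 6:30736605-30739388), Grb10 (4.84, 11:12024855-12026960) and Commd1 with Zrsr1 (4.76, 11:22971670-22973113). Gnas had the most covered sequence, 6750 bp in 7 peaks, and Grb10 had 5533 bp in 8 peaks. The strongest peak of 15 members lay within 2 kb of the outer gene start. Pairs of members shared their strongest peak, Nap1l5 and Herc3 at 4.51, Nnat and Blcap at 4.08, Airn and Igf2r at 4.08, Snurf and Snrpn at 4.59, Mcts2 and H13 at 2.51, and Kcnq1ot1 and Kcnq1 at 3.58. The strongest peak of Peg3 (4.13) lay in its body and within 2 kb of Usp29, outside that gene. The other members with a peak were Impact (4.51), Ube3a (4.35), Trappc9 (3.92), Peg13 (3.83), Cdkn1c (3.75), Meg3 (3.72), Slc38a4 (3.58), Inpp5f, Peg10, Peg12 and Sgce (each 3.41), Magel2 (3.35), Ndn (3.07) and Rian (2.51). The 10 members without a peak were H19, Igf2, Copg2, Rasgrf1, Zim1, Mkrn3, Phlda2, Dlk1, Mirg and Ascl2. The nearest peak was 3131 bp from H19, at 7:142581275-142581611, and 3097 bp from Igf2, and for 7 of the 10 it was within 50 kb.

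Vomeronasal receptors, the pheromone receptors of the vomeronasal organ, had a peak in 71 of 326 members (21.8%), against a mean of 21.2 (3.34-fold, adjusted permutation p = 0.0012). Replicate 1 gave 98 members and replicate 2 gave 99. Vmn2r60 (7:42107770-42196208) had 12 peaks over 6086 bp with a highest enrichment value of 4.18, followed by Vmn1r73 (4272 bp, 5.10), Vmn2r93 (3410 bp, 3.58), Vmn2r103 (2962 bp, 3.58) and Vmn1r74 (2844 bp, 3.92). With peaks at -log10 q of at least 5 the list kept 6 members (adjusted permutation p = 0.941) and within 2 kb of the gene start 23 (adjusted permutation p = 0.106). The other alternatives by shifts gave adjusted permutation p from 0.0012 to 0.0036, and Fisher's exact test gave an adjusted p of 4.38e-12.

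Clustered enzymes of drug metabolism (Cyp2, Cyp3 and Ugt genes) had a peak in 19 of 69 members, against a mean of 6.06 (3.14-fold, adjusted permutation p = 0.0432). Ugt1a7c, Ugt1a10, Ugt1a8, Ugt1a6b and Ugt1a5 had the most covered sequence, from 11027 to 11871 bp. They share 7 peaks at the 3' part of the Ugt1a cluster, the strongest at 1:88204493-88205202 with a value of 4.76. Of the 19 members, 9 are Ugt1a genes that overlap the same domain, 1:88204493-88257948. As a symbol family, tested after the data were seen, Ugt had a peak in 9 of 22 members (mean 2.1) and did not pass (unadjusted permutation p = 0.0864). Killer cell lectin-like receptors, surface receptors of natural killer cells, had a peak in 9 of 26 members, against a mean of 0.995 (9.04-fold, adjusted permutation p = 0.0432). Klra17 (6:129831154-129876672) had 12 peaks over 5331 bp with a highest value of 5.10, followed by Klrb1c (2218 bp, 5.60), Klra4 (1116 bp, 3.41), Klri1 (687 bp, 3.58) and Klra5 (681 bp, 3.41). Both calls were lost with the pooled list (adjusted permutation p = 0.174 for the enzymes and 0.0734 for the receptors) and with the peaks of replicate 2 alone (0.0576 for both) or of replicate 1 alone (0.169 and 0.136). With replicate 2 alone the excess was 2.06-fold for the enzymes and 4.78-fold for the receptors. With replicate 1 alone it was 1.68-fold and 3.15-fold. Over the alternatives by shifts the adjusted permutation p ran from 0.00384 to 1 for the enzymes and from 0.0416 to 0.251 for the receptors. Fisher's exact test, which does not allow for clustered genes, gave adjusted p of 2.59e-05 and 0.001.

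Olfactory receptors had a peak in 87 of 1092 members, against a mean of 36.4, and did not pass (2.39-fold, adjusted permutation p = 0.0631). Against other protein-coding genes by Fisher's exact test the direction turned (0.897-fold, adjusted p = 0.39). Olfr398 had 2890 bp covered, Olfr344 had 1903 bp and Olfr1349 had 1810 bp. The list passed with the pooled list (204 members, adjusted permutation p = 0.0115) and with either replicate alone (0.0326 for replicate 2, 0.0115 for replicate 1), and the adjusted p ran from 0.0115 to 1 over its alternatives. Genes of the germ line and meiosis had a peak in 6 of 32 members and did not pass (mean 2.26, adjusted permutation p = 0.125). Ddx4 (5.27), Stag3 (4.25) and Dazl (2.72) each had their strongest peak within 2 kb of the outer gene start. Counted at gene starts alone, 5 members of this list had a peak, which passed (adjusted permutation p = 0.0016), as did the pooled list with 15 members (adjusted permutation p = 0.0168), and the adjusted p ran from 0.0016 to 1 over its alternatives.

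None of the remaining lists, among them genes chosen for the forebrain and for other cell types and organs, passed in either direction for members with a peak. Transcription factors of the embryonic forebrain had one in 2 of 44 members, Sox5 (7 peaks, highest value 3.92) and Bcl11b (3.92), with adjusted permutation p = 1. Genes of neural progenitors and neurons had one in 5 of 33 members (mean 6.84, adjusted permutation p = 0.946), among them Nrxn1 (4.42), Nfib (2.87) and Snap25 (3.27). Genes of other cell types and organs gave Ank1 (5.18) as 1 of 15 for blood, Pdgfrb (3.16) and Tek (4.52) as 2 of 16 for vessels and mesenchyme, 0 of 21 for microglia and immune cells, and 0 of 33 for other organs. Neither Pdgfrb nor Tek had a peak in replicate 1. Housekeeping genes gave 0 of 31, ribosomal protein genes 0 of 80, Hox genes 0 of 39 and histone genes 0 of 68. The enzymes and partners of H3K9 methylation gave 3 of 23 members with a gene model, Atf7ip (6 peaks, 4.08), Fam208a (5.02) and Morc2a (3.24). Among other gene clusters, defensins gave 2 of 64 (Defb33 at 4.42 and Defb4 at 3.35), keratin-associated proteins 1 of 57 (Krtap10-4 at 3.02) and serpins 1 of 50 (Serpinb6d at 3.35). X-linked germline genes gave 1 of 69 (Rhox13 at 3.41) and major urinary proteins 0 of 22. The adjusted p of the lists in this paragraph was 0.619 or more. With Fisher's exact test, which does not allow for clustered or short genes, histone genes (adjusted p = 0.0121) and ribosomal protein genes (adjusted p = 0.00388) had fewer members with a peak. Counts this small leave room for differences the test could not detect.

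Merging peaks within 5 kb of each other gave 6048 domains with a median length of 476 bp. Of these, 1395 held at least 2 peaks, 73 held at least 10, and the rest were single peaks. The lists are of narrow peaks, which can split broad regions of the mark. These lengths are therefore those of called peaks and not of the full extent of H3K9me3. The 100 longest held 19.8% of the peak sequence. The longest, 18:37654760-37777669, was 122910 bp long with 76 peaks and covered the variable exons of the gamma protocadherins from Pcdhga1 to Pcdhga12. Protocadherins also held the domains at 18:36898916-36980017 (Pcdha1 to Pcdha7), 18:37469370-37538938 (Pcdhb15 to Pcdhb22) and 18:36988742-37031505 (Pcdha8 to Pcdha12). The domain at 13:65237043-65297763 held Zfp369 and Gm10775 with 36 peaks, and that at 1:88204493-88257948 held the 3' part of the Ugt1a cluster, Dnajb3 and Mroh2a with 15 peaks. The others among the 10 longest were 13:61259543-61315966 over Gm49398, 4:144427473-144477494 over 1700012P22Rik, Gm9944 and Aadacl3, and 2 without a protein-coding gene, 16:3231545-3284915 and 4:121997309-122050578. The number of domains moves with the number of peaks called and has no test.

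Among the 10 peaks with the highest enrichment values, 6:30957032-30959182 (9.65) covered Klf14, a single-exon zinc finger transcription factor gene, and 4:62191137-62193605 (9.65) covered Zfp37. The peak at 7:12010281-12010952 (10.3) lay 25799 bp from Vmn1r77, that at 4:146480404-146481103 (9.65) lay over Gm26573 and Gm13245 and 10111 bp from Zfp992, and that at 9:19399532-19400456 (9.48) lay 20862 bp from Olfr847. The remaining 5 lay on unplaced or unlocalised scaffolds, with values from 9.15 to 11.3.

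Peak summits lay more often in promoters and exons than under the shifts. Promoters, within 2 kb of a transcript start, held 14.1% of 9853 peaks on the chromosomes (exact 95% interval 13.4 to 14.8), against 8.67% under 1000 shifts, and exons held 4.92% (4.50 to 5.37), against 2.68%. Introns held 32.9% (32 to 33.8), against 39.1%. The adjusted p of these classes was 0.00266, from an unadjusted p of 0.002, the smallest the shifts can give, and both replicates gave the same directions and calls. Intergenic sequence held 48.0% (47.1 to 49.0), against 49.5% (adjusted permutation p = 0.472). These intervals take peaks as independent, which neighbouring peaks are not. Over the shifts the share ran from 6.97% to 11.2% for promoters, 2.01% to 3.53% for exons, 33.2% to 45.6% for introns and 43.2% to 56.0% for intergenic sequence. The promoter class took starts of any gene type and came before exons, so summits in exons near a start counted in it. Within 2 kb of the outer gene start, 48 of 56 clustered protocadherins had a peak (mean 0.537 under the shifts). Of 424 zinc finger genes, 12 had one there (mean 7.9). How far single gene groups make up the promoter excess was not tested. With peaks at -log10 q of at least 5 the intron class lost its call (33.4%, adjusted permutation p = 0.12) and the intergenic class gained one (36.5%, adjusted permutation p = 0.00266); over the alternatives the adjusted p ran from 0.00266 to 0.12 for introns and from 0.00266 to 0.488 for intergenic sequence.

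Chromosome 7 was the richest in peaks, with 1478, or 10.2 per Mb, followed by chromosomes 17 (7.05 per Mb), 4 (6.40), 18 (5.56) and 13 (5.34), while the median autosome had 3.39 and chromosome 15, the lowest, had 1.86. Chromosome X had 97 peaks, or 0.567 per Mb, which was 0.167 of the autosome median. X ranked below all 19 autosomes in each of the 4 lists, at 0.267 of the median in replicate 1, 0.258 in replicate 2 and 0.260 in the pooled list. An exact permutation over the 20 chromosomes, in which the smallest two-sided p is 0.05, gave p = 0.1, since chromosome 7 lay farther from the mean of the others than X did. Among peaks at -log10 q of at least 5 the ratio was 0.405 and 3 autosomes lay below X. The Y chromosome had 6 peaks.

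**Figure D3:**
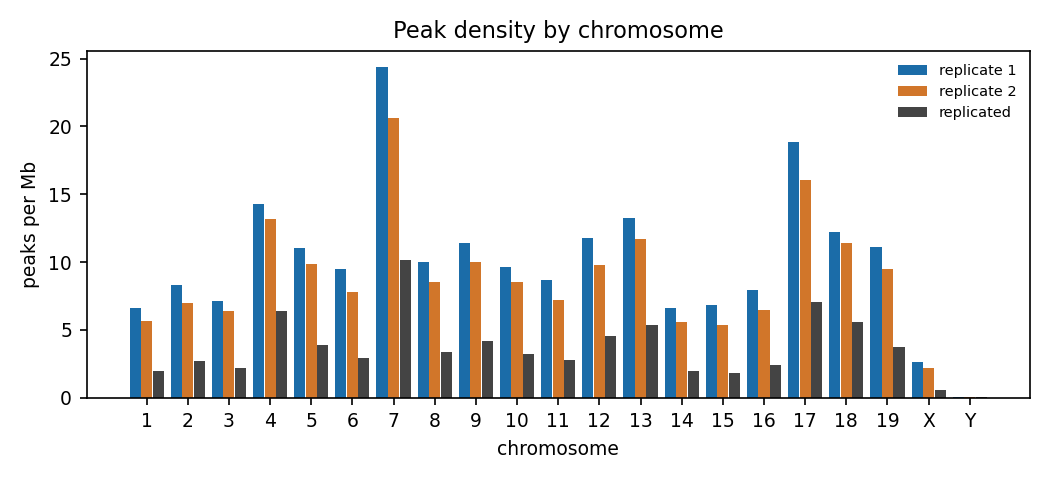
Peaks per Mb of chromosome length for each chromosome (x axis) in replicate 1, replicate 2 and the replicated list. Chromosome 7 is the highest of the bars in each list, at 10.2 per Mb in the replicated list, and X is the lowest apart from Y, at 0.567.

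The sequence under the peaks was richer in G and C and poorer in repeat-masked bases than under 100 shifts. GC content was 44.0%, against 42.1%, and the soft-masked share was 23.5%, against 33.8% (permutation p = 0.0198 for each, the smallest the shifts can give). Both replicates gave these directions, with a masked share of 23.1% in replicate 1 and 25.7% in replicate 2. The ratio of observed to expected CpG was 0.187, against 0.194 (permutation p = 0.119). It lay below the shifts in each replicate's own list (0.181 and 0.175, permutation p = 0.0198 for each) and above them for peaks at -log10 q of at least 5 (0.263, p = 0.0198).

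Peaks of the replicates overlapped far more than moved lists, though most peaks of each list were found in that replicate alone. Replicate 2 overlapped 7921 of 27248 replicate 1 peaks (29.1%, exact 95% interval 28.5 to 29.6), against 0.576% under 1000 shifts, and replicate 1 overlapped 7686 of 23478 replicate 2 peaks (32.7%, 32.1 to 33.3), against 0.665%. The Jaccard index by length was 0.151, against 0.0016 (two-sided permutation p = 0.002 for each of these, the smallest the shifts can give). The share found rose with the enrichment value, from 20.8% in the lowest quartile of replicate 1 to 46.5% in the highest, and from 24.7% to 49.5% in replicate 2. Of the peaks at -log10 q of at least 5, 402 of 456 in replicate 1 (88.2%, 84.8 to 91.0) and 664 of 788 in replicate 2 (84.3%, 81.5 to 86.7) were found in the whole list of the other replicate. With both lists held to that threshold the shares were 52.4% and 28.6%, and with the same number of strongest peaks by p from each list they were 27.9% and 26.7%. Across the 7921 shared peaks, which are not independent of their neighbours, the enrichment values of the replicates had a Spearman rho of 0.185 and a Pearson r of 0.297. Replicate 2 had the higher value in 68.7% of them.

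**Figure D4:**
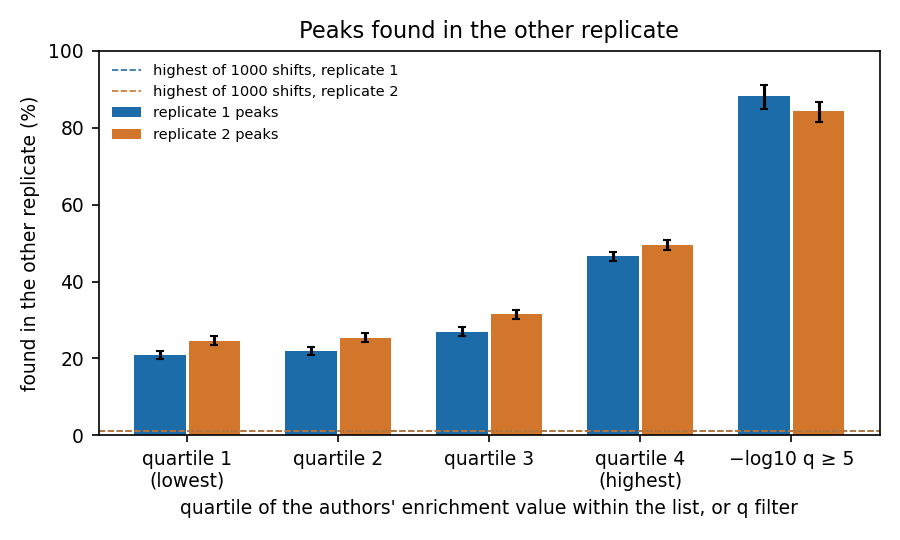
Percent of the peaks of each replicate found in the other (y axis), by quartile of the enrichment value within its list and for peaks with -log10 q of at least 5, with exact 95% intervals. Dashed lines give the highest whole-list share among 1000 shifts, 1.02% and 1.16%, and the highest quartiles reach 46.5% and 49.5%.

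Every peak of the replicated list was a pooled peak, and the list kept 27.2% of the pooled peaks (exact 95% interval 26.7 to 27.6). It kept 7.75% of the pooled peaks in the lowest quartile of enrichment and 68.9% in the highest, and 1.02% of the narrowest quartile and 71.2% of the widest. A rule of 1 bp of overlap with both replicates' deposited lists would keep 7565 pooled peaks, of which 7302 were in the replicated list, so that 2743 of its peaks (27.3%) had no overlapping peak in at least 1 replicate's list. A rule of 50% of the pooled peak would keep 4068, all of them in the replicated list. A q of at most 0.05 was reached by 90.3% of replicated peaks, 51.6% of pooled peaks, 27.7% of replicate 1 peaks and 36.3% of replicate 2 peaks.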

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

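The test of the peaks with the smallest p and that of masked sequence on X were chosen only after the result was seen; the other tests on X were written down before.

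Peaks on scaffolds were left out of the comparisons with moved lists and of the replicates with each other, and those on Y were included in them with no result of their own beyond their number. On unplaced or unlocalised scaffolds the replicated list had 192 peaks, on 19 scaffolds, with 293 in replicate 1 and 242 in replicate 2. JH584304 held 55 of them, GL456393 held 32 and GL456239 held 23. A -log10 q of at least 5 was reached by 69.3% of scaffold peaks and by 12.8% of peaks on chromosomes. On the Y chromosome there were 6 peaks, 4 of them between 90737410 and 90742285.

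Of the 10 peaks with the smallest p, several lay in the 45S ribosomal RNA unit or on a scaffold. The smallest was at 17:39843003-39846802 (-log10 p of 157, enrichment value 3.93), in the annotated genes Gm26917 and CT010467.1, a stretch known to hold the 45S ribosomal RNA unit, and 5 of the 10 smallest lay on the scaffold JH584304. The 2224 replicated peaks with an enrichment value within 5% of that of the first peak had a median -log10 p of 7.43. The median enrichment value of the 10 was 4.11, at percentile 82.1 of the list, but 3 of the 10 were above the 95th percentile of 4.93 (2 on JH584304, at 10.1 and 9.50, and 5:146260855-146261493 at 6.61). Copies piled onto 1 reference position could give a small p without a high ratio, which holds for 7 of the 10 and not for these 3, so that explanation stays open and no biological explanation was tested because the design holds 1 group.

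Chromosome X had the lowest peak density of X and the autosomes in all 4 lists. Against more repeat-masked sequence on X as the whole cause, X stayed lowest per Mb of unmasked sequence, at 0.216 of the autosome median (1.11 peaks per Mb, with 2.86 in the lowest autosome). Against a lack of the gene families that carry peaks, X stayed lowest without peaks within 50 kb of the lists that passed, at 0.179 of the median (0.515 per Mb, with 1.77 in the lowest autosome). Fewer copies of X in a pool of both sexes could remove mainly weak peaks. Among peaks at -log10 q of at least 5 the ratio was predicted to be at least 0.5 if copies were the cause. It was predicted to be below 0.5 if not. The ratio was 0.405, on the side written down against copies. The Poisson interval of its 30 peaks, 0.273 to 0.578, includes 0.5, so the explanation stays open. That interval was added after the ratio was seen and takes peaks as independent, which neighbouring peaks are not. The design, with both sexes in each pool, gives no comparison of sexes.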

How the results depend on the processing

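The alternative of replicated peaks that overlap a peak of each replicate and that of peaks placed at random within their own gene were chosen only after the data were examined. Of 305 pairs of a result and an alternative, 231 kept their direction and their side of the threshold, or stayed within the limit for a value or count without a test. Higher overlap of the replicates than under shifts held in all alternatives run, as did the higher promoter and exon shares, the higher GC content, the lower masked share and the last exon share of zinc finger genes. Protocadherins and imprinted genes passed under all alternatives, and zinc finger genes under all but promoters alone. With the pooled list the domains numbered 19889 and the CpG ratio, 0.171, passed its test. Leaving out a replicate gave 14168 to 17415 domains and a CpG ratio of 0.175 to 0.181, which passed. With -log10 q of at least 5 there were 806 domains, the intron share was 33.4% and lost its call, the intergenic share was 36.5% and gained one, and the CpG ratio reversed to 0.263. With reciprocal overlap of 50% the Spearman rho of shared peaks was 0.229. Overlap rules of 1 bp and 50% with both replicates would keep 20.5% and 11.0% of the pooled peaks. With promoters alone 3 lists passed, and with Fisher's exact test 2 lists, histone and ribosomal protein genes, had fewer members with a peak. The other reversals were between calls that did not pass on either side, 35 of them in gene lists, most with few members hit. The intergenic share reversed to 52.1% with the pooled list and to 50.6% to 50.7% with a single replicate. Members with a peak, where the direction against the mean changed, were as follows. The pooled list gave 2 keratin-associated proteins, 9 serpins, 1 blood gene and 4 genes of H3K9 methylation. Single replicates, both given where the direction changed in either, gave 2 to 5 Hox genes, 1 to 4 keratin-associated proteins and 4 to 11 serpins. They also gave 2 X-linked germline genes in each, 1 to 2 blood genes, 2 to 3 vessel and mesenchyme genes and 4 to 6 genes of H3K9 methylation. With -log10 q of at least 5 there were 0 keratin-associated proteins, 0 defensins and 0 X-linked germline genes. With overlap of each replicate there were 0 vessel and mesenchyme genes. Promoters alone gave 0 keratin-associated proteins, 1 serpin, 0 blood genes and 0 vessel and mesenchyme genes, and gene bodies without extension 0 keratin-associated proteins and 2 genes of H3K9 methylation. Fisher's exact test changes the mean and not the count. By it there were 87 olfactory receptors, 1 keratin-associated protein, 2 defensins, 1 X-linked germline gene, 5 neural genes and 1 blood gene. With at least 500 bp covered there were 0 keratin-associated proteins, 0 X-linked germline genes, 2 forebrain transcription factors, 0 blood genes and 0 vessel and mesenchyme genes. The domain counts follow from the number of peaks in each list; for the other changes the cause was not tested. Read depth is unknown, so whether deeper libraries would raise the overlap of the replicates cannot be read from these files.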

Other observations

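The count of C-type exons and the tests of symbol families, of gene types and of masked sequence 5 to 10 kb from peaks were chosen only after the data were seen; the tests of primer binding sites, of the zinc finger linker and of the 500 bp beside peaks were written down before their results.

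The first exons of the C-type protocadherins, which neurons express without the random choice of the other isoforms, held no peak: 0 of 5 had one, against 49 of 51 first exons of the other members. The 51 include 22 of the beta cluster. Replicate 1 gave 0 of 5 against 49 of 51 and replicate 2 gave 0 of 5 against 51 of 51. The median covered share of the other first exons was 90.2% in the gamma cluster, 61.4% in the alpha cluster and 25.1% in the beta cluster. The beta exons ran from 2588 bp (Pcdhb1) to 8695 bp (Pcdhb14), and the gamma exons from 2542 bp (Pcdhgb2) to 2961 bp (Pcdhga12). The beta share thus rests on unlike lengths and cannot be set directly against the others. The 5 C-type exons lie beside each other at the ends of 2 clusters, so they are few independent places.

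Among 257 families formed from the first letters of gene symbols, with at least 10 members each, 3 had more members with a peak than under 10000 shifts and 0 had fewer (12 had an unadjusted p below 0.05). These were Pcdhb (21 of 22, mean 0.397), Zfp (121 of 394, mean 31.8) and Vmn (71 of 330, mean 21.5), each with an adjusted p of 0.0171. Pcdhga had a peak in 12 of 12 members and did not pass (mean 2.52, adjusted p of 1); its members share peaks and 1 place. A first count of 2000 shifts could not have reached the threshold and was raised. Families with an unadjusted p below 0.05 that did not pass included Klra (6 of 11, adjusted permutation p = 0.283), Skint (9 of 11, 0.291), Nlrp (8 of 17, 0.291), Scgb (9 of 34, 0.642), Ceacam (6 of 15, 0.792) and Wdr, the sole one below its shifts (1 of 64, mean 6.54, 0.474). By gene type, immunoglobulin variable gene segments had a peak in the gene body in 15 of 218 cases, against a mean of 0.596 under 500 shifts (adjusted permutation p = 0.016), unprocessed pseudogenes in 79 of 2642 (mean 31.4, 0.0255) and processed pseudogenes in 98 of 9940 (mean 44.6, 0.016). Transcribed unprocessed pseudogenes (23 of 253, 0.016) and miscellaneous RNA genes (10 of 562, 0.016) passed as well, and protein-coding genes did not (1771 of 21938, mean 1696, 0.249).

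Zinc finger coding sequence was also found under peaks from the sequence alone. The linker peptide between C2H2 fingers was encoded under 139 peaks (1.41%), against a mean of 5.04 and at most 21 under 1000 shifts. Of these, 92 lay in named zinc finger genes, 20 in other protein-coding genes, among them 2610008E11Rik, Repin1 and Bcl11b, 15 in pseudogenes and 10 in no gene. Of 409 arrays of at least 5 linkers in the genome, 87 (21.3%, exact 95% interval 17.4 to 25.6) had a peak, as had 119 of 1023 of at least 1 linker (11.6%) and 29 of 175 of at least 10 (16.6%); arrays were not compared with shifts. Peaks may thus mark this coding sequence beyond the symbols of the gene list, a hypothesis found and tested on the same peaks.

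Few peaks, but more than under the shifts, lay near a match to the primer binding site of a tRNA, a sign of retroviral sequence that needs no repeat annotation and was not compared with one, taken as the last 15 bases of the tRNA gene with its added end. Within 2 kb, 190 peaks (1.93%) had such a site, against a mean of 60.6 and at most 104 under 1000 shifts. Sites for proline tRNA, the primer of several retrovirus families of mouse, were near 51 peaks, against a mean of 3.08 (16.6-fold, adjusted permutation p = 0.008 over 8 tRNAs). Leucine (47), serine (43), phenylalanine (49) and lysine (11) also passed, and glutamine, glycine and isoleucine did not. Of 201 proline sites, 38 (18.9%, exact 95% interval 13.7 to 25) had a peak within 2 kb, against 171 of 4158 sites of any kind (4.11%). Retroviral elements with such a site may be among the places that carry H3K9me3 here, and elements without an intact site could not be counted.

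The peaks held less masked sequence than moved peaks, and 2 explanations were compared. The 500 bp on each side had a masked share of 33.9%, within the range of the shifts, whose highest was 36.3%, which was written down as the result that would speak against a loss of reads in repeats. That prediction was too narrow, since the labels give a size range of 300 to 500, so fragments from a peak can reach into masked sequence beside it, and the share rose with distance: 36.2% from 1 to 2 kb (highest shift 36.1%), 38.4% from 2 to 5 kb (36.2%) and 39.98% from 5 to 10 kb (36.2%). Peaks may be the unmasked parts of regions rich in masked sequence, but a loss of reads in repeats could leave the same picture, and these values do not separate the 2. Whether reads in repeats were removed by the authors is not given in the sources used here, and no biological explanation was tested.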
